A study of Mus musculus with 26 samples.

How the data were processed

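Polyadenylated RNA from whole epithelial preparations of the mouse proximal small intestine was sequenced as paired-end reads on a NovaSeq X Plus, per the labels. Villin-CreERT2 drove deletion after tamoxifen, and controls, littermate and sex-matched, were Cre-negative given tamoxifen or Cre-positive given oil, per the labels' protocols. Cre activity and deletion thus go together in every comparison with controls. Reads were aligned with HISAT2 2.2.1 and counted with featureCounts 2.0.1, per the submitters' processing notes. The FPKM values were computed from those counts and deposited by the authors in 4 tables. The notes name the mouse genome builds GRCm39 and mm10 without saying which table used which, so no coordinates are given. No strand setting for the counting is given.

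The tables held 16827 genes (day 6 SMAD1/5, after 34 repeated symbols were dropped), 15653 (day 30 SMAD), 17112 (SMAD4) and 18155 (TBX3, after 9 repeated symbols were dropped). No test crossed tables, since each was normalised on its own. Within each table, genes with an FPKM of at least 1 in as many libraries as the smallest genotype group were kept, 0.5 was added, and values were taken to log2. Changes in genes whose FPKM lay near 0 depend on that pseudocount. Linear models with a mean-variance trend were fitted with limma 3.58.1 in R 4.3.3, with p adjusted by Benjamini and Hochberg over all genes of a comparison and a threshold of 0.05. The 10 libraries of the day 30 SMAD table were fitted together, with the 5 controls as 1 group. Gene lists with at least 4 tested members were tested with camera from limma, at the preset correlation of 0.01 between genes and again with a correlation estimated from the data, adjusted over the lists of a comparison. The share of a list's members past the threshold is given with p adjusted over all genes and over the list alone. Figures and depths were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

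The gene lists, the comparisons and the rule for naming genes were written before the data were examined, as were the alternatives except those that the closing part names as chosen later. The rule took the targeted genes, the 8 genes with the largest rise and the 8 with the largest fall past the threshold, and up to 4 members per list of smallest adjusted p. Of the rises and falls, only genes whose groups did not overlap, with a mean FPKM of at least 5 in the higher group and without a predicted-gene symbol, were taken. Listed members that a comparison across tables needed were added. Genes named outside the rule are said to have been chosen after their values were seen.

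Fragment totals were not among the data analysed here. The smallest step between FPKM values of genes of known exon length gave approximate totals for 3 of the 4 tables, and the depth of the SMAD4 table is unknown, so no counting intervals are given. The procedure was tested on simulated data with the spread of the real libraries. Of 100 genes changed 2-fold, 70% were recovered in the day 6 iDKO comparison, 60% in iDKO at day 30, 79% in iTKO, 75% in iTKO against iDKO, 13% in SMAD4 iKO and 61% in TBX3 iKO, with 2 to 21 false calls among the unchanged genes of a comparison.

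The labels number the replicates without saying whether equal numbers are pairs. Residual correlations of libraries with equal numbers were checked before calls were compared. At day 6 in the SMAD1/5 table they were 0.143, 0.583 and 0.221, all above 0.1, though library 1 and library 3 of the iDKO group correlated more with other controls, and with the replicate block limma called 1924 genes higher and 1031 lower. In the SMAD4 table, where 2 numbers allow a single value, the correlation was 0.283. In the TBX3 table they were -0.151, -0.312 and -0.010, and in the day 30 SMAD table they had mixed signs, so numbers were not taken as pairs there.

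The alternatives tried were other pseudocounts, no filter and a stricter filter, median-centred and quantile-normalised values, limma without the trend and with a robust prior, the replicate block, controls of the same line alone, a fit on the compared groups alone, and each library left out in turn. Splits of the same libraries into other groups were counted for comparisons with at least 3 libraries per group. Genes were not compared across tables by level, and per-animal sex was used only as a covariate. Changes measured for 2 of the genes called are not reported here.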

Results

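Gene expression was measured by RNA sequencing in epithelium of the mouse proximal small intestine after tamoxifen-inducible deletion of BMP pathway genes in the epithelium (Villin-CreERT2). SMAD1 and SMAD5 carry the BMP signal into the nucleus, SMAD4 is the partner they share with the TGF-beta pathway, and TBX3 is a T-box transcription factor. The 26 libraries came in 4 separately normalised tables. The day 6 SMAD1/5 table held 3 control libraries and 3 libraries labelled iDKO (Smad1 and Smad5 deleted together). The day 30 SMAD table held 5 controls, 2 libraries labelled iDKO and 3 labelled iTKO (Smad1, Smad4 and Smad5 deleted). The SMAD4 table held 2 controls and 2 iKO libraries at day 6, and the TBX3 table held 3 controls and 3 iKO libraries at day 30. Days count from the first injection.

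Values were deposited as FPKM, so no total counts were available. The spacing of the FPKM values gave approximate depths, in megafragments (fragments divided by 1e6), of 20.99 to 30.5 per library in the day 6 SMAD1/5 table, 13.1 to 18.1 in the day 30 SMAD table and 10 to 18.6 in the TBX3 table. The depth in the SMAD4 table is unknown. Correlations across genes between libraries of a group were 0.955 to 0.984 in the day 6 SMAD1/5 table, 0.971 to 0.983 in the day 30 SMAD table, 0.969 to 0.972 in the SMAD4 table and 0.959 to 0.978 in the TBX3 table. Paneth cell genes were low in the number 2 libraries of both groups at day 6, with list medians of -3.63 (control) and -3.53 (iDKO) on the log2 scale against the mean of the controls. In the SMAD4 table the number 2 libraries stood at -1.77 and -1.63. In the sentences that follow, levels are mean ± SD in FPKM, mutant against control, and log2 changes carry their standard error. The group sizes given above are the n of each value.

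The targeted genes were read in every library first. Smad4 stood at 7.19 and 5.11 FPKM in the 2 SMAD4 iKO libraries against 24.9 and 22.9 in their controls, and at 35.3, 32.1 and 46.7 in the 3 iTKO libraries against 136 to 163 and 128 to 160.0 in the SMAD1/5-line and SMAD1/4/5-line controls. Tbx3 stood at 16.9, 7.53 and 22.9 in the 3 TBX3 iKO libraries against 45.5, 53.7 and 56.3 in their controls. Smad1 did not pass the test in any comparison, with 9.24 ± 0.911 against 9.96 ± 0.802 FPKM at day 6 (log2 -0.10 ± 0.11) and 27.8 ± 0.907 against 33.2 ± 4.27 FPKM at day 30 (log2 -0.25 ± 0.16) in the libraries labelled iDKO. Smad5 was higher, not lower, in those libraries, with 11.4 ± 1.53 against 5.95 ± 0.334 FPKM at day 6 (log2 0.88 ± 0.12, limma adjusted p = 0.0041) and 29.3 ± 3.47 against 15.9 ± 0.939 FPKM at day 30 (log2 0.86 ± 0.09, limma adjusted p = 2.2e-04). It was also higher in the libraries labelled iTKO (log2 0.96 ± 0.08, limma adjusted p = 6.5e-05). A gene-level FPKM includes exons outside the deleted part, so it does not check the Smad1 and Smad5 deletions, and the iDKO and iTKO names below rest on the labels.

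**Figure D1:**
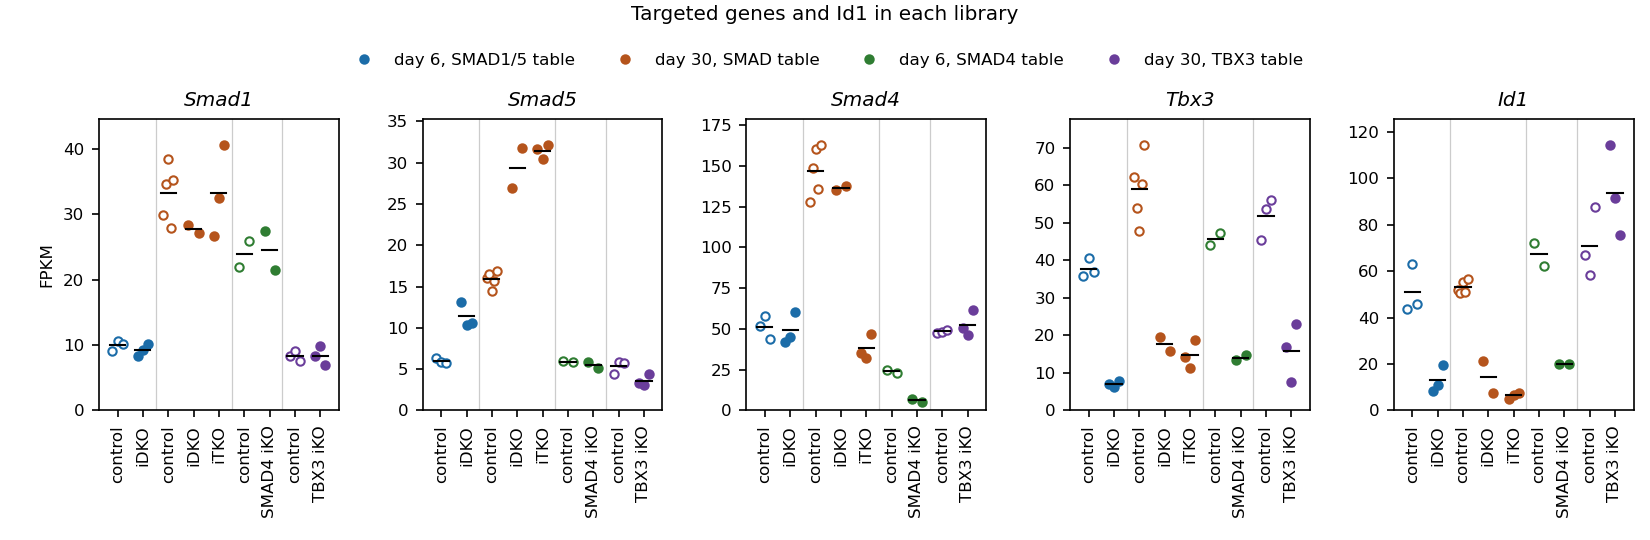
FPKM of Smad1, Smad5, Smad4, Tbx3 and the BMP target Id1 in each of the 26 libraries, with controls as open points, mutants as filled points, the group mean as a line and 1 colour per table. Tbx3 lay below every control of its own table in each library labelled iDKO, iTKO, SMAD4 iKO and TBX3 iKO, and Smad5 lay above every control of its table in each library labelled iDKO and iTKO.

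The day 6 comparison of libraries labelled SMAD1/5 iDKO with controls asked what changed soon after loss of the BMP-activated SMADs. BMP target genes fell. Id1 stood at 13.0 ± 5.82 against 51.0 ± 10.5 FPKM, log2 -1.99 ± 0.30, Id2 at 1.75 ± 0.704 against 19.5 ± 2.12 FPKM, log2 -3.19 ± 0.22, and Smad6, an inhibitor of the pathway, at 0.932 ± 0.241 against 7.31 ± 1.01 FPKM, log2 -2.45 ± 0.18. Tbx3 fell to 7.06 ± 0.716 against 37.8 ± 2.43 FPKM (log2 -2.34 ± 0.10, limma adjusted p = 1.3e-04), and Maf, a transcription factor of mid-villus enterocytes, to 10.6 ± 1.04 against 59.1 ± 8.39 FPKM (log2 -2.41 ± 0.13). Nutrient transporters fell with them, among them the peptide transporter Slc15a1 (80.1 ± 2.48 against 361 ± 11.9 FPKM, log2 -2.16 ± 0.09) and the glucose transporter Slc5a1 (303 ± 19.6 against 1157 ± 84.0 FPKM, log2 -1.93 ± 0.12).

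Of 8 BMP response genes tested at day 6, 1 rose, 5 fell and 2 did not pass the test (1 and 5 adjusted over the list alone). The BMP list had a median log2 of -1.25 (camera adjusted p = 8.9e-05, adjusted p = 0.172 with an estimated correlation), and its median was -0.48 with no filter and -1.99 under the stricter one. The riser was Hes1 (log2 1.12 ± 0.32), also a Notch target and named here after its value was seen, and its call ended without control 1 (log2 1.22), iDKO 1 (1.15), iDKO 2 (1.25) or iDKO 3 (0.95). Of 16 amino acid and peptide transport genes, 0 rose, 14 fell and 2 did not pass the test (0 and 15 adjusted over the list alone). The calls included Slc43a2 (-2.27) and Slc16a10 (-1.79), and the list had a median log2 of -1.48 (camera adjusted p = 8.1e-18, adjusted p = 0.109 with an estimated correlation). Of 12 carbohydrate genes, 0 rose, 8 fell and 4 did not pass the test (0 and 9 adjusted over the list alone). Those called included the glucose transporter Slc2a2 (-1.70) and the fructose transporter Slc2a5 (-1.18), and the list had a median log2 of -0.93 (camera adjusted p = 9.7e-08, adjusted p = 0.336 with an estimated correlation). Xenobiotic metabolism genes, which clear foreign compounds, fell too. Of 24, 1 rose, 17 fell and 6 did not pass the test (1 and 18 adjusted over the list alone), and the cytochrome P450 gene Cyp3a11 dropped to 14.5 ± 7.93 against 571 ± 111 FPKM, log2 -5.36 ± 0.35. The xenobiotic list had a median log2 of -1.23 (camera adjusted p = 5.2e-12, adjusted p = 0.369 with an estimated correlation). Cyp2c29 (0.376 ± 0.311 against 109.5 ± 42.8 FPKM, log2 -6.95 ± 0.35) and the sugar transporter family gene Slc5a4a (0.480 ± 0.264 against 74.1 ± 2.53 FPKM, log2 -6.29 ± 0.20) are uncertain, since near-identical family members can share their reads.

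Tuft and signalling genes moved at day 6, while 0 of 14 goblet genes passed. Of 12 tuft cell genes, 0 rose, 8 fell and 4 did not pass the test (0 and 10 adjusted over the list alone). Called members included Ptgs1 (-1.17), and the list had a median log2 of -0.93 (camera adjusted p = 2.6e-07, adjusted p = 0.369 with an estimated correlation). Of 8 TGF-beta and activin response genes, 5 rose, 0 fell and 3 did not pass the test (7 and 0 adjusted over the list alone). The calls included Pmepa1 (2.60), Tgif1 (1.27) and Skil (1.06), feedback regulators of that pathway, and the list had a median log2 of 0.42 (camera adjusted p = 0.0045, adjusted p = 0.369 with an estimated correlation), with 0.25 left after median centring. Of 22 lipid absorption genes, 2 rose, 7 fell and 13 did not pass the test (5 and 8 adjusted over the list alone), with falls of the fatty acid transporter Cd36 (-1.86) and the apolipoprotein Apoc3 (-1.73). The lipid absorption list had a median log2 of -0.29 (camera adjusted p = 0.0046, adjusted p = 0.556 with an estimated correlation), and its call ended with quantile normalization (median -0.19). Of 19 interferon response genes, 6 rose, 0 fell and 13 did not pass the test (6 and 0 adjusted over the list alone). Those called included Ifi44 (3.15) and Ifit2 (2.81), and the list had a median log2 of 0.76 (camera adjusted p = 0.0116, adjusted p = 0.654 with an estimated correlation). Its call ended without control 3 (median 0.55) or iDKO 2 (0.63). Of 25 cell cycle genes, 3 rose, 0 fell and 22 did not pass the test (1 and 0 adjusted over the list alone), and the replication clamp gene Pcna (0.77) was among those called. The cell cycle list had a median log2 of 0.72 (camera adjusted p = 0.0035, adjusted p = 0.654 with an estimated correlation), with a median of 0.39 without control 2. Of genes taken by the naming rule, the largest rises were in Anxa10 (3.98), Sptssb (3.602), Tmem229b (3.54) and Capg (3.34).

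Among 18 enteroendocrine genes at day 6, 1 rose, 2 fell and 15 did not pass the test (1 and 2 adjusted over the list alone), where the hormone gene Sct fell (6.84 ± 0.451 against 40.0 ± 3.03 FPKM, log2 -2.46 ± 0.10) and the hormone gene Pyy rose (14.1 ± 8.08 against 2.70 ± 0.121 FPKM, log2 2.04 ± 0.37). The list had a median log2 of -0.17 (camera adjusted p = 0.0091, adjusted p = 0.654 with an estimated correlation). Its call ended without iDKO 2 (median 0.19), a library low in Paneth genes, without both libraries low in these genes (0.04) and under the stricter filter (-0.07). Of 14 Paneth genes, 0 rose, 0 fell and 14 did not pass the test (0 and 0 adjusted over the list alone), with a median log2 of -0.55 across libraries that differed widely in these genes within each group. Markers of T cells and intraepithelial lymphocytes, which lie within the epithelium, had a median log2 of -0.51 (camera adjusted p = 1.6e-04, adjusted p = 0.558 with an estimated correlation). Of these, 0 rose, 0 fell and 14 did not pass the test (0 and 0 adjusted over the list alone), and the median was -0.24 without iDKO 3. Of 17 villus tip genes, 1 rose, 5 fell and 11 did not pass the test (1 and 5 adjusted over the list alone), and the list's median (0.06) and mean (-0.14) differed in sign from each other. Its test pointed down (camera adjusted p = 0.0369, adjusted p = 0.558 with an estimated correlation), and adjusted p was 0.0652 with the replicate block and 0.0130 to 0.558 over all alternatives. The median became -0.11 after median centring, and the call also ended without control 2 (median 0.15), iDKO 1 (0.19) or iDKO 3 (0.08). The villus tip transcription factor Klf4 fell (37.3 ± 2.55 against 94.6 ± 6.89 FPKM, log2 -1.33 ± 0.10).

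In limma's test of 10827 genes at day 6, 1681 were higher and 894 lower in the libraries labelled iDKO, and 353 and 382 of these changed more than 2-fold. The median log2 of all genes lay at 0.184, and with each library centred on its median the split became 767 higher and 1193 lower, against 1117 and 1162 with quantile normalization, so that the share higher went from 65.3% to 39.1% and 49.0%. Without iDKO 3 there were 590 higher and 502 lower, without iDKO 2 there were 702 and 583, without control 3 there were 755 and 598, and without iDKO 1 there were 903 and 710. Leaving out both libraries low in Paneth genes gave 1071 and 649 and ended the call of Id1 (log2 -1.76). Camera also called, with genes that rose and fell, median log2 and its range over all alternatives, bile acid and ileal genes (1 and 3 of 6, -1.04, -1.21 to -0.33), ribosomal proteins (2 and 0 of 23, 0.49, 0.25 to 0.64), MHC class II (0 and 0 of 7, -0.49, -0.69 to -0.26), oxidative phosphorylation (0 and 0 of 21, -0.10, -0.27 to 0.00), purine catabolism (0 and 3 of 10, -0.11, -0.28 to 0.04) and Wnt targets (0 and 2 of 10, -0.34, -0.56 to -0.11). Their camera adjusted p was 0.0046 to 0.0452, and adjusted p = 0.369 to 0.654 with an estimated correlation, and at least 1 other alternative ended each call but the first 2.

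At day 30 the comparison of 2 libraries labelled iDKO with the 5 controls asked what held or appeared weeks after the loss. BMP targets and nutrient transporters were again lower, and so were genes of secretory lineages. Id2 stood at 3.73 ± 0.531 against 19.2 ± 2.54 FPKM, log2 -2.22 ± 0.16, and Tbx3 at 17.8 ± 2.58 against 59.0 ± 8.61 FPKM, log2 -1.70 ± 0.19 (limma adjusted p = 2.5e-04). The Paneth cell antimicrobial peptide gene Defa24 stood at 2696 ± 10.1 against 7599.6 ± 1469.5 FPKM, log2 -1.48 ± 0.25, and the secretin gene Sct at 10.8 ± 3.66 against 37.9 ± 7.36 FPKM, log2 -1.78 ± 0.24. Cholesterol synthesis genes were higher, among them Cyp51 (154 ± 55.9 against 35.6 ± 9.09 FPKM, log2 2.10 ± 0.31) and Srebf2, the transcription factor that switches this pathway on (106 ± 9.53 against 54.6 ± 4.33 FPKM, log2 0.95 ± 0.11).

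Of 14 Paneth genes at day 30, 0 rose, 11 fell and 3 did not pass the test (0 and 13 adjusted over the list alone). Called members included Itln1 (-1.52), and the list had a median log2 of -1.29 (camera adjusted p = 1.1e-07, adjusted p = 0.276 with an estimated correlation). Defa24 is uncertain, since near-identical defensin genes can share its reads. Of 22 enteroendocrine genes, 0 rose, 10 fell and 12 did not pass the test (0 and 14 adjusted over the list alone). The calls included Nts (-2.39), Tph1 (-1.36) and Pcsk1 (-1.25), and the list had a median log2 of -0.73 (camera adjusted p = 8.2e-08, adjusted p = 0.192 with an estimated correlation). Of 15 goblet cell genes, 0 rose, 10 fell and 5 did not pass the test (0 and 11 adjusted over the list alone). Those called included Atoh1, the secretory lineage transcription factor (-0.90), and the mucus genes Tff3 (-0.79) and Zg16 (-1.09), and the list had a median log2 of -0.64 (camera adjusted p = 1.1e-05, adjusted p = 0.192 with an estimated correlation). Markers of T cells and intraepithelial lymphocytes moved with these groups. Of 16, 0 rose, 9 fell and 7 did not pass the test (0 and 11 adjusted over the list alone). Called members included Cd3g (-0.88) and Gzma (-1.25), and the list had a median log2 of -0.82 (camera adjusted p = 5.2e-06, adjusted p = 0.293 with an estimated correlation). Of 14 tuft cell genes, 0 rose, 1 fell and 13 did not pass the test (0 and 1 adjusted over the list alone). The tuft cell list had a median log2 of -0.67 (camera adjusted p = 0.014, adjusted p = 0.661 with an estimated correlation), and its call ended without iDKO 2 (median -0.51) and under the stricter filter (-0.79). B and plasma cell markers did not pass as a list (median log2 -0.05, camera adjusted p = 0.825), nor did myeloid markers (-0.18, camera adjusted p = 0.37).

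Of 20 cholesterol synthesis genes at day 30, 14 rose, 0 fell and 6 did not pass the test (16 and 0 adjusted over the list alone). The list had a median log2 of 0.99 (camera adjusted p = 6.8e-07, adjusted p = 0.293 with an estimated correlation). Of 9 BMP response genes, 0 rose, 6 fell and 3 did not pass the test (1 and 7 adjusted over the list alone). The calls included Id1 (-1.998), Id3 (-2.09) and Smad6 (-1.89), and the list had a median log2 of -0.97 (camera adjusted p = 1.1e-04, adjusted p = 0.192 with an estimated correlation). Of 16 amino acid and peptide transport genes, 0 rose, 14 fell and 2 did not pass the test (0 and 15 adjusted over the list alone). Those called included Slc15a1 (-2.05) and Slc16a10 (-1.94), and the list had a median log2 of -1.42 (camera adjusted p = 3.9e-12, adjusted p = 0.192 with an estimated correlation). Of 12 carbohydrate genes, 0 rose, 7 fell and 5 did not pass the test (0 and 7 adjusted over the list alone). Called members included Slc5a1 (-1.31) and Treh (-1.33), and the list had a median log2 of -0.75 (camera adjusted p = 2.7e-05, adjusted p = 0.293 with an estimated correlation). Of 24 xenobiotic genes, 1 rose, 13 fell and 10 did not pass the test (1 and 13 adjusted over the list alone). The calls included Cyp2b10 (-4.34), Cyp3a11 (-3.996) and Aldh1a1 (-1.76), and the list had a median log2 of -0.87 (camera adjusted p = 2.9e-06, adjusted p = 0.293 with an estimated correlation). The fatty acid transporter Cd36 fell (-2.39), while lipid genes did not pass as a list (median log2 -0.12, camera adjusted p = 0.557).

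Lists with a positive median at day 30 included 19 interferon response genes, of which 5 rose, 0 fell and 14 did not pass the test (12 and 0 adjusted over the list alone). Ifi44 stood at 46.2 ± 5.47 against 1.66 ± 0.256 FPKM, log2 4.43 ± 0.17. The list had a median log2 of 1.06 (camera adjusted p = 1.4e-06, adjusted p = 0.293 with an estimated correlation). It rested mainly on iDKO 1 (0.30 without it, near tamoxifen controls at 0.153 and 0.284, and 1.73 without iDKO 2). Of 10 TGF-beta and activin response genes, 5 rose, 0 fell and 5 did not pass the test (5 and 0 adjusted over the list alone). Those called included Pmepa1 (3.20) and Skil (0.96), and the list had a median log2 of 0.48 (camera adjusted p = 5.2e-04, adjusted p = 0.182 with an estimated correlation). Of 10 fetal and regenerative genes, 4 rose, 0 fell and 6 did not pass the test (7 and 0 adjusted over the list alone), with Clu (3.53) and Ly6d (3.36) among them. The fetal and regenerative list had a median log2 of 1.13 (camera adjusted p = 6.0e-04, adjusted p = 0.293 with an estimated correlation), and this list call ended without iDKO 1 (median 0.31). Of 11 Wnt targets, 0 rose, 3 fell and 8 did not pass the test (0 and 6 adjusted over the list alone). Called members included the stem cell transcription factor Ascl2 (-1.40) and the feedback gene Axin2 (-0.94), and the list had a median log2 of -0.48 (camera adjusted p = 0.0121, adjusted p = 0.293 with an estimated correlation). The Wnt target call ended under the stricter filter (median -0.01). Among single genes, the iron exporter Slc40a1 rose (77.2 ± 10.1 against 7.72 ± 2.17 FPKM, log2 3.27 ± 0.30), and so did Ctrb1, a digestive protease gene of the exocrine pancreas (43.5 ± 29.8 against 0.117 ± 0.111 FPKM, log2 5.99 ± 0.37). The gluconeogenic enzyme gene Pck1 fell (log2 -4.54 ± 0.88).

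In limma's test of 11939 genes, 1126 were higher and 1112 lower in the libraries labelled iDKO at day 30, and 337 and 423 of these changed more than 2-fold. Against the 2 SMAD1/5-line controls alone, which also received tamoxifen, 649 were higher and 625 lower. Without iDKO 1, which stood apart on the second principal component, 474 were higher and 431 lower. Calls that ended without iDKO 1, given with the log2 change then left, included those of Ifit2 (2.77), Pck1 (-3.23), Mmp7 (-0.83), Ly6d (1.41), Ifit1 (1.24) and Aldoc (0.67). Those that ended without iDKO 2 were Tff3 (-0.59), Zg16 (-0.89), Gzma (-0.85), Klf4 (-0.88) and Aldoc (0.60), and the call of Ly6d also ended without control 2 (3.18) or control 3 (3.17). Of 7 bile acid and ileal genes, 1 rose, 3 fell and 3 did not pass the test (1 and 3 adjusted over the list alone), with a median log2 of -0.55 (camera adjusted p = 0.0494, adjusted p = 0.274 with an estimated correlation), a list call that 11 other alternatives ended.

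**Figure D2:**
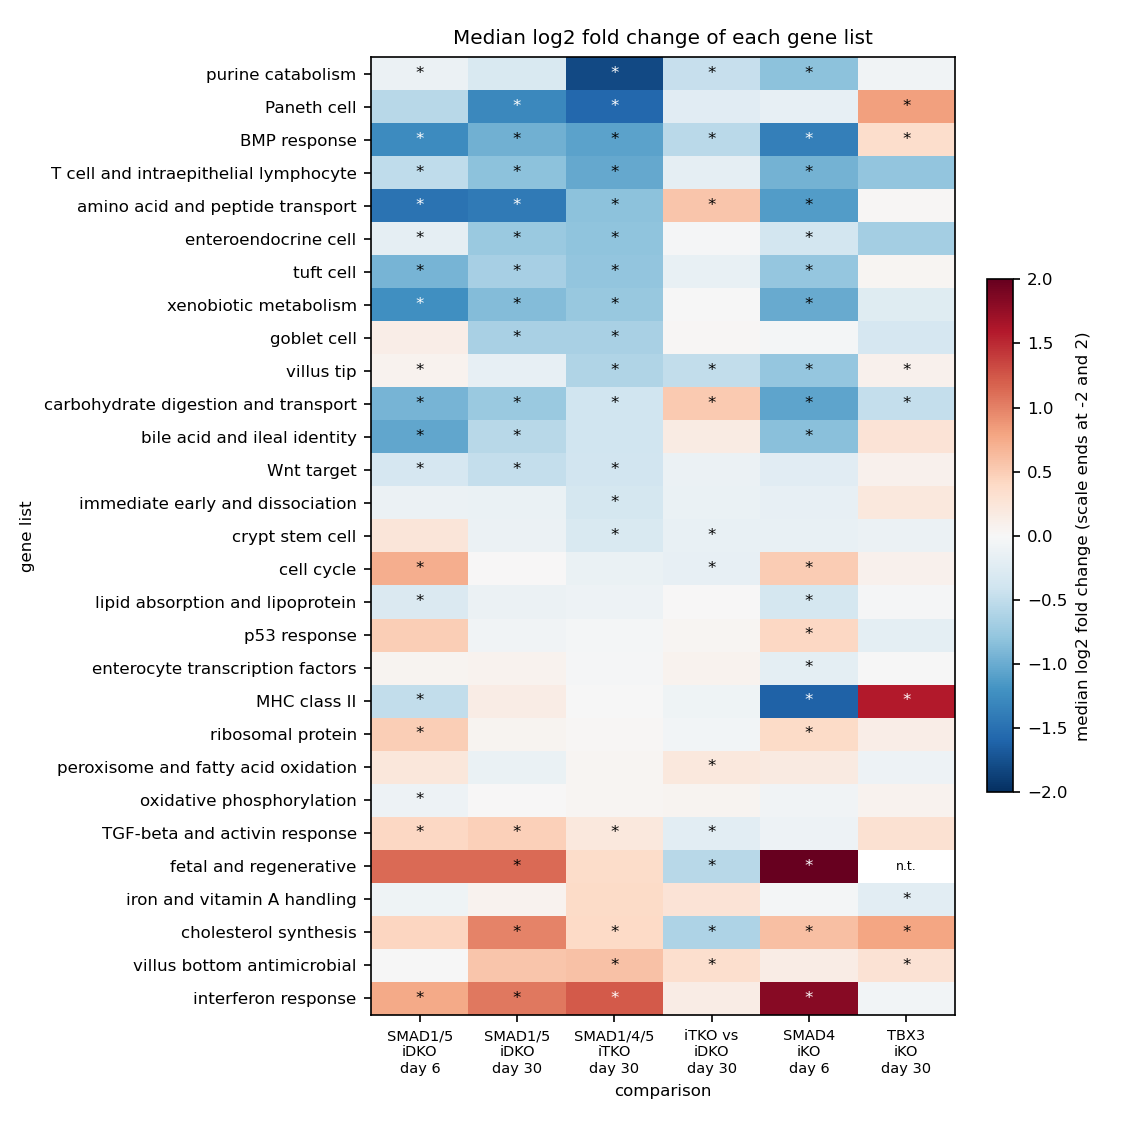
Median log2 fold change of each gene list with at least 4 tested members (rows) in the 6 comparisons (columns), from blue (lower) to red (higher), with a star where camera's adjusted p with the preset correlation passed 0.05 and n.t. where a list was not tested. BMP response genes had negative medians in the 4 comparisons of SMAD mutants with controls (between -1.36 and -0.97, and between -2.88 and -0.40 over all alternatives), and no list passed with an estimated correlation in any comparison.

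The comparison of the 3 libraries labelled SMAD1/4/5 iTKO with the 5 controls at day 30 asked what removal of SMAD4 together with SMAD1 and SMAD5 gave. BMP targets fell, with Id1 at 6.47 ± 1.32 against 53.1 ± 2.68 FPKM, log2 -2.96 ± 0.25, and Smad6 at 0.8291 ± 0.482 against 19.1 ± 4.99 FPKM, log2 -3.91 ± 0.26. Villus tip genes of purine breakdown fell as well, with Ada, which deaminates adenosine, at 41.7 ± 12.7 against 667 ± 164 FPKM, log2 -3.999 ± 0.21 (limma adjusted p = 2.6e-06) and Nt5e, which makes adenosine from AMP, at 1.91 ± 0.647 against 27.3 ± 13.9 FPKM, log2 -3.44 ± 0.33. Antimicrobial genes of the villus bottom were higher, with Reg3g at 6818 ± 1545 against 2039 ± 960.0 FPKM, log2 1.86 ± 0.37, and Lypd8 at 3610.4 ± 1015 against 1031 ± 231 FPKM, log2 1.79 ± 0.22. Tbx3 stood at 14.7 ± 3.88 against 59.0 ± 8.61 FPKM, log2 -1.99 ± 0.17 (limma adjusted p = 6.1e-05).

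Of 9 BMP response genes in the libraries labelled iTKO, 0 rose, 6 fell and 3 did not pass the test (0 and 6 adjusted over the list alone). The BMP response list had a median log2 of -1.07 (camera adjusted p = 2.8e-05, adjusted p = 0.145 with an estimated correlation). Of 10 purine catabolism genes, 0 rose, 6 fell and 4 did not pass the test (1 and 7 adjusted over the list alone). The calls included Slc28a1 (-3.68) and Enpp3 (-2.80), and the list had a median log2 of -1.81 (camera adjusted p = 5.3e-06, adjusted p = 0.187 with an estimated correlation), with -1.03 left with no filter. Of 17 villus tip genes, 1 rose, 10 fell and 6 did not pass the test (2 and 11 adjusted over the list alone). Those called included Klf4 (-1.58), and the list had a median log2 of -0.60 (camera adjusted p = 8.5e-06, adjusted p = 0.187 with an estimated correlation). Several of these, Ada, Nt5e and Enpp3 among them, are on the purine and villus tip lists alike. Of 13 villus bottom antimicrobial genes, 7 rose, 0 fell and 6 did not pass the test (9 and 0 adjusted over the list alone). The villus bottom antimicrobial list had a median log2 of 0.58 (camera adjusted p = 4.2e-05, adjusted p = 0.145 with an estimated correlation). Of 19 interferon response genes, 14 rose, 0 fell and 5 did not pass the test (17 and 0 adjusted over the list alone). Called members included Ifi44 (4.51) and Ifit1 (1.88), and the list had a median log2 of 1.23 (camera adjusted p = 1.6e-08, adjusted p = 0.208 with an estimated correlation). Of 16 amino acid and peptide transport genes, 0 rose, 11 fell and 5 did not pass the test (0 and 13 adjusted over the list alone). The calls included Slc6a19 (-1.75) and Slc15a1 (-1.39), and the list had a median log2 of -0.82 (camera adjusted p = 6.1e-08, adjusted p = 0.195 with an estimated correlation). Of 24 xenobiotic genes, 2 rose, 13 fell and 9 did not pass the test (2 and 16 adjusted over the list alone). Those called included Cyp2b10 (-4.37) and Cyp3a11 (-4.22), and the list had a median log2 of -0.76 (camera adjusted p = 1.8e-07, adjusted p = 0.187 with an estimated correlation).

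Secretory groups were lower in the libraries labelled iTKO too. Of 14 Paneth genes, 0 rose, 13 fell and 1 did not pass the test (0 and 13 adjusted over the list alone). Called members included Itln1 (-1.64), Defa24 (-1.60) and Mmp7 (-1.003), and the list had a median log2 of -1.57 (camera adjusted p = 2.7e-10, adjusted p = 0.187 with an estimated correlation). Of 22 enteroendocrine genes, 0 rose, 13 fell and 9 did not pass the test (0 and 14 adjusted over the list alone), with the neurotensin gene Nts at 1.84 ± 0.508 against 31.4 ± 7.19 FPKM, log2 -3.76 ± 0.30. The enteroendocrine cell list had a median log2 of -0.81 (camera adjusted p = 6.6e-10, adjusted p = 0.145 with an estimated correlation). Of 15 goblet genes, 0 rose, 10 fell and 5 did not pass the test (0 and 11 adjusted over the list alone). The calls included Tff3 (-0.80) and Zg16 (-1.07), and the list had a median log2 of -0.64 (camera adjusted p = 2.1e-06, adjusted p = 0.145 with an estimated correlation). Of 14 tuft cell genes, 0 rose, 1 fell and 13 did not pass the test (0 and 6 adjusted over the list alone), and the list had a median log2 of -0.79 (camera adjusted p = 4.4e-04, adjusted p = 0.44 with an estimated correlation). Markers of T cells and intraepithelial lymphocytes moved with them. Of 16, 0 rose, 13 fell and 3 did not pass the test (0 and 13 adjusted over the list alone). Those called included Cd3g (-1.30) and Gzmb (-1.39), and the list had a median log2 of -1.02 (camera adjusted p = 1.7e-08, adjusted p = 0.187 with an estimated correlation). Of 11 Wnt targets, 0 rose, 6 fell and 5 did not pass the test (0 and 6 adjusted over the list alone). Called members included Ascl2 (-2.18) and Axin2 (-1.39), and the list had a median log2 of -0.38 (camera adjusted p = 5.3e-04, adjusted p = 0.187 with an estimated correlation).

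Of 11939 genes tested with limma, 1090 were higher and 1069 lower in the libraries labelled iTKO, and 215 and 365 of these changed more than 2-fold. Without iTKO 3 the counts were 593 and 653, and Dmbt1 (log2 0.94) and Lct (-1.48) were no longer called. The call of Cyp51 (log2 1.097 ± 0.27) ended without iTKO 1 (1.05) or iTKO 2 (0.91). The cholesterol synthesis list (0.40, camera adjusted p = 0.0122, adjusted p = 0.591 with an estimated correlation) lost its call without iTKO 2 (median 0.20). The crypt stem cell list (-0.30, camera adjusted p = 0.0309, adjusted p = 0.498 with an estimated correlation) lost it without iTKO 1 (-0.26), iTKO 3 (-0.23), control 3 (-0.28) or control 4 (-0.29). Camera also called, with genes that rose and fell, median log2 and its range over all alternatives, TGF-beta and activin response genes (4 and 0 of 10, 0.21, 0.17 to 0.41), carbohydrate genes (0 and 2 of 12, -0.40, -0.44 to -0.27) and immediate early genes (0 and 6 of 18, -0.36, -0.44 to -0.19). Their camera adjusted p was 0.024 to 0.048, and adjusted p = 0.187 to 0.572 with an estimated correlation, and each call ended in at least 1 other alternative.

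The libraries labelled iTKO were compared directly with those labelled iDKO to ask what the added loss of SMAD4 changed. Smad4 itself was lower (38.0 ± 7.64 against 136 ± 1.80 FPKM, log2 -1.85 ± 0.16, limma adjusted p = 4.5e-04). The adenosine genes Ada (41.7 ± 12.7 against 505 ± 3.87 FPKM, log2 -3.63 ± 0.26, limma adjusted p = 1.3e-04) and Nt5e (1.91 ± 0.647 against 27.1 ± 1.01 FPKM, log2 -3.55 ± 0.41) were lower, as were Pmepa1, a feedback inhibitor of TGF-beta signalling (16.1 ± 1.76 against 78.3 ± 14.3 FPKM, log2 -2.24 ± 0.15), and the tight junction gene Cldn4 (4.90 ± 2.19 against 67.1 ± 20.6 FPKM, log2 -3.70 ± 0.37). Ctrb1 was lower (0.256 ± 0.193 against 43.5 ± 29.8 FPKM, log2 -5.70 ± 0.41). The largest rises among genes taken by the naming rule were those of Unc93a2 (1.53), Slc5a11 (1.34), Hsd17b6 (1.26) and Slc2a7 (1.25), the last a sugar transporter.

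Of 10 purine catabolism genes, 0 rose, 4 fell and 6 did not pass the test (0 and 5 adjusted over the list alone). The calls included Slc28a2 (-2.22) and Alpi (-0.97), and the list had a median log2 of -0.47 (camera adjusted p = 2.9e-04, adjusted p = 0.444 with an estimated correlation). Of 17 villus tip genes, 0 rose, 3 fell and 14 did not pass the test (0 and 9 adjusted over the list alone). The villus tip list had a median log2 of -0.49 (camera adjusted p = 8.5e-08, adjusted p = 0.375 with an estimated correlation), with -0.28 left without iDKO 1. Of 10 TGF-beta and activin response genes, 0 rose, 2 fell and 8 did not pass the test (0 and 2 adjusted over the list alone), with Itgb6 (-1.19) beside Pmepa1. The TGF-beta and activin response list had a median log2 of -0.22 (camera adjusted p = 0.0028, adjusted p = 0.283 with an estimated correlation), with -0.07 left without iTKO 1 and -0.08 without iTKO 3. Cholesterol synthesis genes had a median of -0.62 on the log2 scale, and 0 rose, 0 fell and 20 did not pass the test (0 and 0 adjusted over the list alone), with camera adjusted p = 2.3e-07, adjusted p = 0.48 with an estimated correlation. Amino acid and peptide transport genes had a median of 0.56, and 0 rose, 0 fell and 16 did not pass the test (1 and 0 adjusted over the list alone), with camera adjusted p = 8.5e-08, adjusted p = 0.444 with an estimated correlation. For carbohydrate genes the median was 0.52, and 0 rose, 0 fell and 12 did not pass the test (2 and 0 adjusted over the list alone), with camera adjusted p = 2.0e-04, adjusted p = 0.48 with an estimated correlation. These 3 medians rested in part on iDKO 1. Without it they were -0.27, 0.20 and 0.24, with the list calls kept. Without iDKO 2 the first 2 were -0.95 and 0.92, and without iTKO 3 the first was -0.41. The fetal and regenerative gene Clu (-2.53) and the nuclear receptor gene Pparg (-2.19) were also lower.

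With limma, 26 of 11939 genes were higher and 65 lower in iTKO than in iDKO. As a difference of effects, each genotype against its own line's controls, 0 were higher and 7 lower, with 886 genes at an unadjusted p under 0.05 (1366 in the direct comparison), and with only the 5 libraries compared in the fit 5 were higher and 18 lower. The counts rested on single libraries, with 1 higher and 20 lower without iDKO 1, 153 and 161 without iDKO 2, 8 and 42 without iTKO 1, 8 and 29 without iTKO 2, and 3 and 29 without iTKO 3. Of the 27 genes taken for this comparison, the calls of 17 ended without iDKO 1, 1 without iDKO 2, 7 without iTKO 1, 10 without iTKO 2 and 12 without iTKO 3, while Ada, Nt5e, Ctrb1, Cldn4, Pmepa1 and Smad4 passed without any 1 library. The replicate block ended the calls of Nt5e and Smad4, and the difference of effects those of Nt5e and Cldn4, with log2 changes at the weakest of -3.29 (Nt5e), -1.73 (Smad4) and -3.21 (Cldn4) over all alternatives. Camera also called, with genes that rose and fell, median log2 and its range over all alternatives, BMP response genes (0 and 1 of 9, -0.53, -0.78 to -0.18), fetal and regenerative genes (0 and 1 of 10, -0.56, -1.35 to -0.12), villus bottom antimicrobial genes (0 and 0 of 13, 0.34, 0.27 to 0.57), peroxisome genes (0 and 0 of 22, 0.21, 0.15 to 0.34), cell cycle genes (0 and 0 of 25, -0.16, -0.32 to -0.06) and crypt stem cell genes (0 and 0 of 20, -0.16, -0.24 to -0.12). Their camera adjusted p was 0.0028 to 0.0166, and adjusted p = 0.444 to 0.835 with an estimated correlation, and each call ended in at least 1 other alternative.

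SMAD4 iKO libraries were compared with oil-injected controls at day 6 to ask what loss of the shared SMAD partner gave. BMP targets were lower, with Id1 at 19.98 ± 0.223 against 67.3 ± 7.03 FPKM, log2 -1.72 ± 0.14, and Id3 at 9.61 ± 0.258 against 77.0 ± 11.9 FPKM, log2 -2.93 ± 0.16. Tbx3 fell to 14.03 ± 0.964 against 45.7 ± 2.28 FPKM, log2 -1.67 ± 0.14 (limma adjusted p = 0.0138), and the lactase gene Lct to 32.6 ± 8.32 against 408 ± 87.6 FPKM, log2 -3.63 ± 0.24. Interferon response genes were higher, with Usp18 at 54.0 ± 10.2 against 7.23 ± 0.0701 FPKM, log2 2.80 ± 0.18, and Oas2, a sensor of viral RNA, at 14.6 ± 2.32 against 1.23 ± 0.164 FPKM, log2 3.12 ± 0.20. Genes of MHC class II, which presents antigen, were lower, with H2-Aa at 247 ± 92.8 against 950.3 ± 54.2 FPKM, log2 -1.99 ± 0.27.

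Of 8 BMP response genes in SMAD4 iKO, 0 rose, 5 fell and 3 did not pass the test (1 and 5 adjusted over the list alone). Those called included Id2 (-3.05) and Smad6 (-3.29), and the list had a median log2 of -1.36 (camera adjusted p = 2.1e-04, adjusted p = 0.262 with an estimated correlation). Of 19 interferon response genes, 12 rose, 0 fell and 7 did not pass the test (17 and 0 adjusted over the list alone). Called members included Ifit2 (3.47) and Ifit3 (2.67), and the list had a median log2 of 1.83 (camera adjusted p = 1.8e-16, adjusted p = 0.262 with an estimated correlation). Of 7 MHC class II genes, 0 rose, 6 fell and 1 did not pass the test (0 and 7 adjusted over the list alone). The calls included H2-Ab1 (-1.66) and Ciita (-1.73), which controls the class, and the list had a median log2 of -1.62 (camera adjusted p = 5.6e-08, adjusted p = 0.262 with an estimated correlation). Of 7 fetal and regenerative genes, 4 rose, 0 fell and 3 did not pass the test (7 and 0 adjusted over the list alone). Those called included Ly6d (4.31), Ly6a (3.58) and Areg (2.49), and the list had a median log2 of 2.09 (camera adjusted p = 4.7e-07, adjusted p = 0.262 with an estimated correlation). Of 11 purine catabolism genes, 0 rose, 5 fell and 6 did not pass the test (0 and 9 adjusted over the list alone). Called members included Ada (-1.83), Nt5e (-2.29) and Slc28a1 (-3.08), and the list had a median log2 of -0.83 (camera adjusted p = 8.7e-09, adjusted p = 0.262 with an estimated correlation). Of 17 villus tip genes, 0 rose, 5 fell and 12 did not pass the test (1 and 9 adjusted over the list alone). The calls included Klf4 (-1.38), and the list had a median log2 of -0.78 (camera adjusted p = 4.3e-05, adjusted p = 0.262 with an estimated correlation), with -0.51 left without iKO 2. Paneth genes were low in the number 2 library of each group, and 0 rose, 0 fell and 14 did not pass the test (0 and 0 adjusted over the list alone), with a median log2 of -0.17.

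Some nutrient genes fell in SMAD4 iKO. Of 12 carbohydrate genes, 0 rose, 4 fell and 8 did not pass the test (0 and 10 adjusted over the list alone). Those called included the gluconeogenic enzyme gene Fbp1 (-3.02), and the list had a median log2 of -1.05 (camera adjusted p = 1.9e-09, adjusted p = 0.262 with an estimated correlation). Of 16 amino acid and peptide transport genes, 0 rose, 6 fell and 10 did not pass the test (0 and 14 adjusted over the list alone). Called members included Slc36a1 (-2.38) and Slc15a1 (-1.75), and the list had a median log2 of -1.12 (camera adjusted p = 1.8e-12, adjusted p = 0.262 with an estimated correlation). Of 23 xenobiotic genes, 1 rose, 7 fell and 15 did not pass the test (3 and 16 adjusted over the list alone). The calls included Cyp2b10 (-5.33) and Cyp2c66 (-3.41), and the list had a median log2 of -1.002 (camera adjusted p = 4.3e-08, adjusted p = 0.262 with an estimated correlation). Of 22 lipid genes, 1 rose, 4 fell and 17 did not pass the test (2 and 9 adjusted over the list alone). Those called included Apoc3 (-2.23) and Cd36 (-1.93), and the list had a median log2 of -0.34 (camera adjusted p = 0.0011, adjusted p = 0.262 with an estimated correlation). Of 13 tuft cell genes, 0 rose, 4 fell and 9 did not pass the test (0 and 8 adjusted over the list alone). The tuft cell list had a median log2 of -0.77 (camera adjusted p = 6.2e-08, adjusted p = 0.262 with an estimated correlation), with -1.36 under the stricter filter. Of 15 markers of T cells and intraepithelial lymphocytes, 0 rose, 1 fell and 14 did not pass the test (0 and 12 adjusted over the list alone), with Gzmb the gene called (-1.44). The lymphocyte marker list had a median log2 of -0.94 (camera adjusted p = 4.0e-08, adjusted p = 0.419 with an estimated correlation). Cell cycle genes had a median of 0.50, and 0 rose, 0 fell and 25 did not pass the test (7 and 0 adjusted over the list alone), with camera adjusted p = 4.0e-08, adjusted p = 0.262 with an estimated correlation.

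With limma, 156 of 12202 genes were higher and 261 lower in SMAD4 iKO, and 144 and 222 of these changed more than 2-fold. With 2 libraries per group, the counts were 30 and 38 without control 1, 37 and 39 without control 2, 0 and 11 without iKO 1 (1883 genes at an unadjusted p under 0.05), and 0 and 2 without iKO 2 (1527). The calls of 22 to 45 of the 49 genes taken for this comparison ended, Smad4 and Tbx3 among them each time, although their log2 changes then stayed at -1.66 to -2.12 (Smad4, -1.89 with all libraries) and -1.60 to -1.74 (Tbx3). Controls received oil and mutants tamoxifen, so injection, Cre activity and genotype go together. Simulated 2-fold changes were recovered in 13% of cases here and 4-fold changes in 65%, and at an unadjusted p under 0.05 there were 2539 genes. Camera also called, with genes that rose and fell, median log2 and its range over all alternatives, cholesterol synthesis (0 and 0 of 20, 0.61, 0.31 to 0.93), ribosomal proteins (0 and 0 of 23, 0.38, 0.31 to 0.47), bile acid and ileal genes (1 and 3 of 7, -0.84, -0.89 to -0.30), enteroendocrine cells (0 and 1 of 18, -0.37, -0.80 to -0.04), enterocyte transcription factors (0 and 3 of 34, -0.20, -0.31 to -0.07) and p53 response (1 and 0 of 15, 0.41, 0.21 to 0.66). Their camera adjusted p was 1.2e-08 to 0.0154, and adjusted p = 0.262 to 0.638 with an estimated correlation, and at least 1 other alternative ended each call but the first 2.

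TBX3 iKO libraries were compared with oil-injected controls at day 30 to ask which genes follow loss of this transcription factor, itself lower in each SMAD mutant. MHC class II genes were higher, with H2-Aa at 184 ± 91.3 against 32.2 ± 14.3 FPKM, log2 2.48 ± 0.40, and Cd74, the chaperone of the class, at 673 ± 325 against 151 ± 66.0 FPKM, log2 2.14 ± 0.40. The bile acid receptor gene Nr1h4 rose to 58.1 ± 9.86 against 14.05 ± 1.63 FPKM, log2 2.00 ± 0.16, and the bile acid exporter subunits Slc51a (295 ± 12.2 against 182 ± 11.7 FPKM, log2 0.69 ± 0.10) and Slc51b (255 ± 27.7 against 121 ± 14.1 FPKM, log2 1.07 ± 0.13) rose with it. Fbp1 (8.17 ± 1.35 against 26.4 ± 1.74 FPKM, log2 -1.64 ± 0.14), Apoc3 (409 ± 24.3 against 1067 ± 118 FPKM, log2 -1.38 ± 0.12) and the fatty acid transporter gene Cd36 (28.2 ± 3.70 against 91.6 ± 14.1 FPKM, log2 -1.68 ± 0.15) were lower. Of the genes taken by the naming rule, the largest rises were those of Tbx3os2 (57.4 ± 7.18 against 1.44 ± 0.439 FPKM, log2 4.92 ± 0.19, limma adjusted p = 1.4e-04) and Bmp3, a BMP family ligand (30.3 ± 9.87 against 1.89 ± 0.681 FPKM, log2 3.67 ± 0.28, limma adjusted p = 0.0031). Tbx3os2 lies antisense to Tbx3, and since no strand setting is given for the counting, its reads cannot be told apart from those of Tbx3.

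Of 6 MHC class II genes in TBX3 iKO, 4 rose, 0 fell and 2 did not pass the test (6 and 0 adjusted over the list alone). The calls included H2-DMb1 (1.70), and the list had a median log2 of 1.59 (camera adjusted p = 1.0e-07, adjusted p = 0.318 with an estimated correlation). Of 18 cholesterol synthesis genes, 2 rose, 0 fell and 16 did not pass the test (15 and 0 adjusted over the list alone), with the risers Sqle (1.82) and Hmgcs1 (0.96). The cholesterol synthesis list had a median log2 of 0.79 (camera adjusted p = 1.4e-10, adjusted p = 0.318 with an estimated correlation). Of 12 carbohydrate genes, 0 rose, 4 fell and 8 did not pass the test (0 and 8 adjusted over the list alone). Those called included the disaccharidase genes Lct (-0.89) and Treh (-0.66), and the list had a median log2 of -0.47 (camera adjusted p = 1.8e-06, adjusted p = 0.15 with an estimated correlation). Of 13 villus bottom antimicrobial genes, 1 rose, 0 fell and 12 did not pass the test (5 and 0 adjusted over the list alone), and the riser was Lypd8 (2.21). The villus bottom antimicrobial list had a median log2 of 0.29 (camera adjusted p = 2.5e-04, adjusted p = 0.318 with an estimated correlation), with a median of 0.75 without iKO 3. Of 12 Paneth genes, 0 rose, 0 fell and 12 did not pass the test (0 and 0 adjusted over the list alone). The Paneth list had a median log2 of 0.83 (camera adjusted p = 0.0075, adjusted p = 0.649 with an estimated correlation), and its call ended without control 1 (median 0.53) or iKO 3 (0.53) and under the stricter filter (0.66). Of 17 villus tip genes, 0 rose, 0 fell and 17 did not pass the test (1 and 0 adjusted over the list alone). The villus tip list had a median log2 of 0.09 (camera adjusted p = 0.0415, adjusted p = 0.654 with an estimated correlation), a call that ended in 7 other alternatives, with median centring (0.15) and without iKO 3 (0.01) among them. Of 9 iron and vitamin A genes, 0 rose, 2 fell and 7 did not pass the test (0 and 3 adjusted over the list alone), and both that fell, Retsat (-0.91) and Lrat (-0.86), act on retinol. The iron and vitamin A handling list had a median log2 of -0.21 (camera adjusted p = 0.0344, adjusted p = 0.318 with an estimated correlation), but the list call ended without control 2 (median -0.10) or iKO 2 (-0.32). Of 21 lipid genes, 0 rose, 6 fell and 15 did not pass the test (0 and 6 adjusted over the list alone), and of 6 bile acid and ileal genes, 3 rose, 1 fell and 2 did not pass the test (3 and 1 adjusted over the list alone), while neither passed as a list (camera adjusted p = 0.289 and 0.0634). BMP response genes had a median of 0.35, and 0 rose, 0 fell and 7 did not pass the test (1 and 1 adjusted over the list alone), with camera adjusted p = 0.0412, adjusted p = 0.536 with an estimated correlation, a list call that ended without control 1 (median 0.31), control 2 (0.27), iKO 1 (0.28) or iKO 3 (0.38).

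With limma, 131 of 9794 genes were higher and 204 lower in TBX3 iKO, with 82 and 82 of these changed more than 2-fold, and with each library centred on its median 154 were higher and 135 lower, so that the share higher went from 39.1% to 53.3%. The counts were 44 and 35 without control 1, 36 and 23 without control 2, 25 and 22 without control 3, 52 and 74 without iKO 1, and 83 and 94 without iKO 3, and 6 to 26 of the calls of the 42 genes taken for this comparison ended without a single library. As in the SMAD4 table, injection, Cre activity and genotype go together. Tbx3 itself (15.8 ± 7.76 against 51.8 ± 5.63 FPKM, log2 -1.81 ± 0.36, limma adjusted p = 0.0479) lay just past the threshold, with adjusted p from 0.0191 to 0.169 over the alternatives, and its call ended without control 1 (log2 -1.90), control 2 (-1.78), control 3 (-1.75) or iKO 1 (-1.93).

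The SMAD1/5 effect was set side by side at the 2 times, which share no library. Across 10428 genes, which are not independent replicates, the log2 changes had Pearson's r = 0.80 and Spearman's rho = 0.71. There were 749 genes called higher at both times, where independent lists of these sizes would share 166, and 590 called lower, where they would share 83.4. The gene Aldoc, a glycolytic aldolase, was called in opposite directions, lower at day 6 (4.75 ± 2.16 against 10.8 ± 2.25 FPKM, log2 -1.18 ± 0.34) and higher at day 30 (11.2 ± 0.405 against 7.09 ± 1.17 FPKM, log2 0.63 ± 0.15). It was named after its values were seen, and its call ended at day 6 without control 1 (log2 -1.13), control 2 (-1.06), control 3 (-1.35), iDKO 2 (-1.29) or iDKO 3 (-0.80). At day 30 it ended without iDKO 1 (0.67) or iDKO 2 (0.60). Times and tables differ together, so no gene's change between the times was tested.

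**Figure D3:**
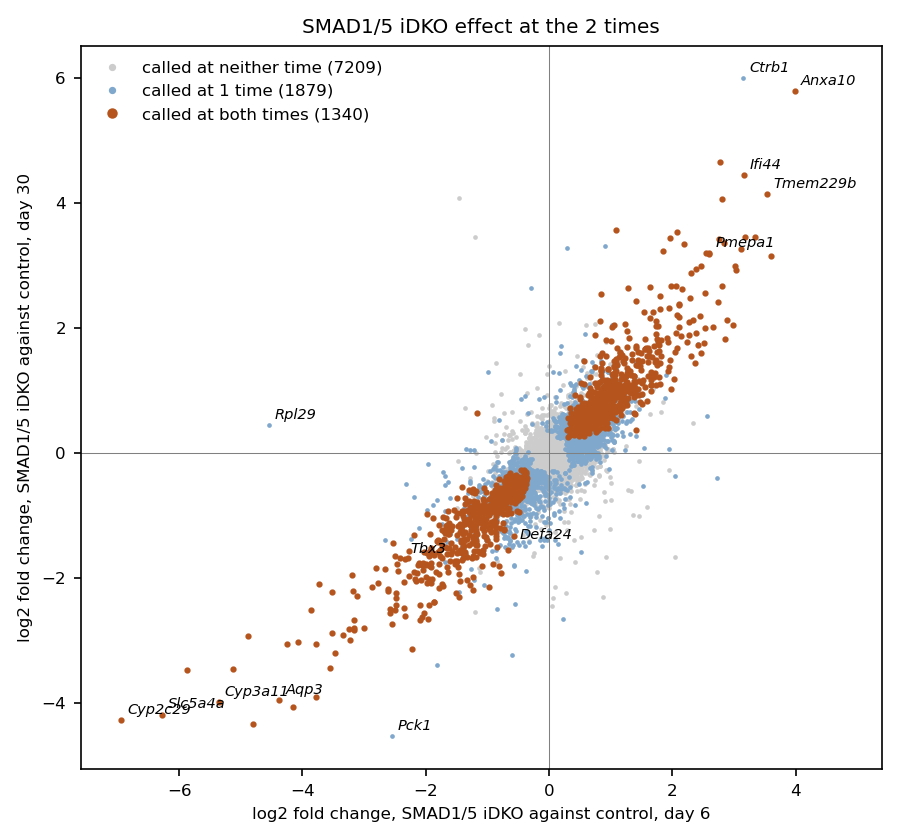
Log2 fold change of each gene tested at both times, libraries labelled SMAD1/5 iDKO against controls, at day 6 (x axis) and day 30 (y axis), coloured by whether limma called the gene at both times, at 1 time or at neither. The points rise along the diagonal (Pearson's r = 0.80), with 749 genes called higher and 590 called lower at both times.

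SMAD4 iKO and SMAD1/5 iDKO libraries at day 6 were compared in the same way, across 10307 genes (Pearson's r = 0.73, Spearman's rho = 0.70). There were 98 genes called higher in both, against 20.6 for independent lists, and 198 called lower in both, against 20.1. As a set, the 865 genes lower in the libraries labelled iDKO had a median log2 of -0.71 in SMAD4 iKO (camera adjusted p = 5.1e-67, adjusted p = 0.0228 with an estimated correlation). The 1621 genes higher in those libraries had a median of 0.31 (camera adjusted p = 8.3e-26, adjusted p = 0.0131 with an estimated correlation).

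At day 30 the iDKO and iTKO effects were measured against the same 5 controls, and their log2 changes had Pearson's r = 0.76 and Spearman's rho = 0.72 across 11939 genes. Simulated unchanged groups against these controls gave a mean r of 0.325. The covariance was 0.237 against a simulated 0.0197, a difference of 0.217. There were 665 genes called higher in both, against 103 for independent lists, and 669 called lower in both, against 99.6. With each genotype set against its own line's controls, so that no library was shared, r was 0.72, with 386 called higher and 406 called lower in both, against 47.6 and 43.7 for independent lists.

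The TBX3 table was read for genes called in iDKO and iTKO libraries. No control had active Cre, and all TBX3 and some day 30 SMAD ones got oil, so shared tamoxifen or Cre effects were not excluded. The 969 genes lower in iDKO at day 30 had a median log2 of -0.24 in TBX3 iKO, with 76.2% of them below 0 (camera adjusted p = 3.4e-09, adjusted p = 0.0158 with an estimated correlation). The 942 genes higher in iDKO had a median of 0.09, with 63.4% above 0 (camera adjusted p = 1.9e-10, adjusted p = 0.0158 with an estimated correlation). The 839 genes lower in iTKO had a median of -0.22 (camera adjusted p = 1.4e-05, adjusted p = 0.0120 with an estimated correlation), and the 949 higher in iTKO a median of 0.068 (camera adjusted p = 3.4e-09, adjusted p = 0.0601 with an estimated correlation). The 852 genes lower in iDKO at day 6 had a median of -0.24 (camera adjusted p = 1.0e-08, adjusted p = 0.0330 with an estimated correlation), and the 1510 higher at day 6 a median of 0.024 (camera adjusted p = 1.0e-05, adjusted p = 0.124 with an estimated correlation). The median of all genes in this table was -0.06. With the 200 genes of largest statistic in each direction, all 6 sets passed with the preset correlation. With an estimated one, the sets lower in iTKO (median -0.32, adjusted p = 0.0591) and lower in iDKO at day 6 (-0.32, adjusted p = 0.0591) lost their calls. The sets higher in iTKO (0.26, adjusted p = 0.0481) and higher in iDKO at day 6 (0.18, adjusted p = 0.0277) passed, as did both day 30 iDKO sets (-0.35, adjusted p = 0.0145, and 0.27, adjusted p = 0.0214).

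**Figure D4:**
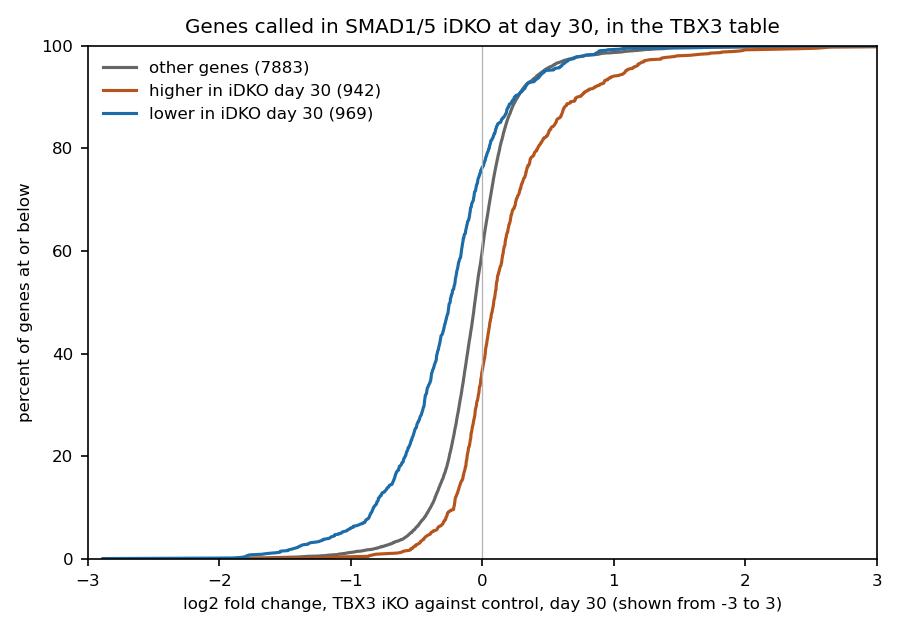
Cumulative percent of genes (y axis) by log2 fold change in TBX3 iKO against control (x axis), for genes called higher or lower in the libraries labelled SMAD1/5 iDKO at day 30 and for the other genes tested. The curve of the 969 genes lower in iDKO lies left of the other genes (median -0.24) and that of the 942 genes higher in iDKO lies right of them (median 0.09).

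Gene by gene, the log2 changes of TBX3 iKO and of iDKO at day 30 had Pearson's r = 0.33 and Spearman's rho = 0.31 across 9441 genes, and for the other 3 SMAD comparisons with controls r was 0.26 to 0.28. There were 95 genes called lower in both, against 20.3 for independent lists, and 51 called higher in both, against 12.6, while 11 were higher in iDKO and lower in TBX3 iKO, against 19.8, and 12 the reverse, against 12.9. Of 137 genes called lower in all 4 comparisons of SMAD mutants with controls, 34 of the 136 tested in TBX3 iKO were called lower there too, among them the xenobiotic gene Cyp2c66 (37.8 ± 7.77 against 88.04 ± 8.63 FPKM, log2 -1.22 ± 0.16), Cubn (-1.57), Cd36 (-1.68) and Apoc3 (-1.38). Of 67 called higher in all 4, of which 54 were tested in TBX3 iKO, 12 were also called higher in TBX3 iKO, with Bmp3 (3.67) and Lypd8 (2.21) among them. The 3 genes lower in the SMAD mutants and higher in TBX3 iKO were Tbx3os2 (4.92), Slc51a (0.69) and Glod5 (0.86), the last named after its value was seen.

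**Figure D5:**
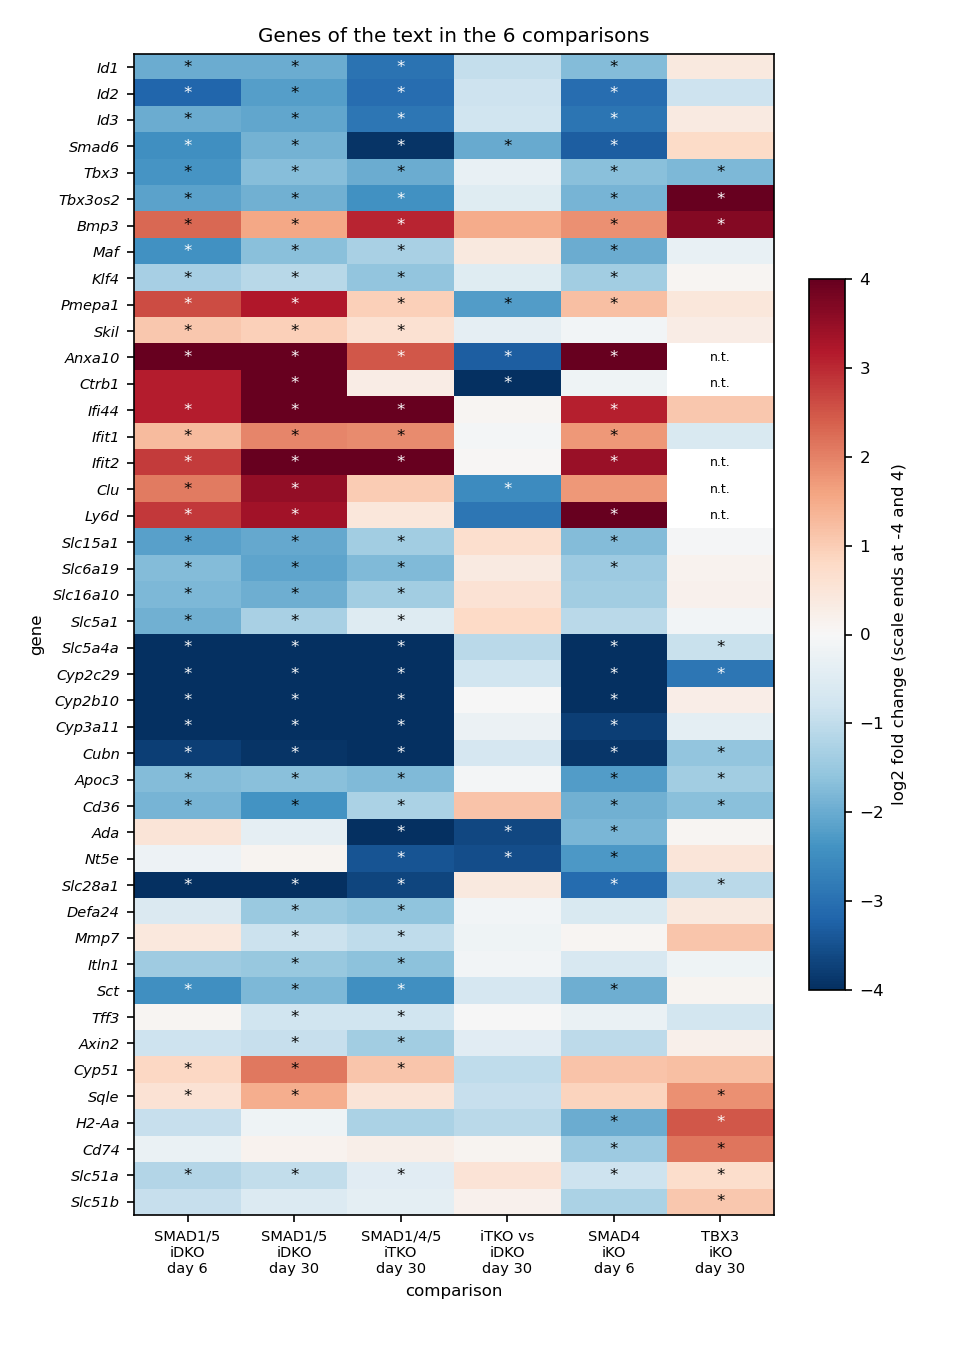
Log2 fold change of genes named in the text (rows) in the 6 comparisons (columns), from blue (lower) to red (higher), with a star where limma's adjusted p passed 0.05 and n.t. where a gene was not tested. Tbx3, Id1, Id2, Id3 and Smad6 were called lower in the 4 comparisons of SMAD mutants with controls, and Bmp3 was called higher in these and in TBX3 iKO.

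The 2 kinds of day 30 control were compared as well, since 2 came from the SMAD1/5 line with tamoxifen and 3 from the SMAD1/4/5 line with oil. With limma, 0 genes were higher and 2 lower in the SMAD1/4/5-line controls, and 629 had an unadjusted p under 0.05. The 2 genes were Gm9625 (log2 -6.17 ± 0.30, adjusted p = 3.6e-05) and Gm8730 (log2 -7.42 ± 0.39, adjusted p = 3.6e-05), both named after their values were seen. Between these controls, interferon response genes had a median log2 of -0.30, xenobiotic genes -0.29 and oxidative phosphorylation genes -0.15 (camera adjusted p = 0.0277 each). B and plasma cell markers had a median of 0.87 (camera adjusted p = 0.0092). Each had adjusted p = 0.988 with an estimated correlation.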

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

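The tests of crypt base content, tamoxifen and pancreas cells below were chosen after the results were seen, while the splits into other groups and the search for far libraries were planned. In the 5 controls of day 30, 72 named genes were searched for a library far from the others, and 3 were found where chance alone gives 3.6. The Paneth protease gene Mmp7 stood at 178 FPKM in SMAD1/4/5-line control 3 against 119 to 130 in the others, the nucleoside transporter gene Slc28a1 at 160.3 in SMAD1/5-line control 1 against 67.0 to 74.9, and the serotonin synthesis gene Tph1 at 9.95 in SMAD1/4/5-line control 3 against 15.7 to 17.7.

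The iTKO and iDKO effects at day 30, each against controls of its own line, differed in limma's test for 7 genes, all lower in iTKO. The differences in log2 were -5.76 for Ctrb1 (adjusted p = 0.0104), -3.16 for Ada (0.0104), -2.51 for Pmepa1 (0.0022), -2.48 for Gprc5a (0.0104), -1.98 for Gm19680 (0.0264), -1.81 for Smad4 (0.0301) and -1.47 for Tlcd2 (0.0264). The direct comparison, which draws on the level of no control and where both mutants received tamoxifen, gave log2 changes of -5.70, -3.63, -2.24, -2.41, -1.78, -1.85 and -1.28 for the same genes. Genotype and line go together in both contrasts. Of 79 named genes compared between times, 2 had opposite changes in every iDKO library. Aldoc was named after its values were seen. Aldoc had a log2 change of 0.63 at day 30 against -1.18 at day 6, and the ribosomal protein gene Rpl29 one of 0.44 (adjusted p = 0.305, not called) against -4.55. Neither difference was tested, times and tables differ together, and reads of Rpl29 can come from its pseudogenes.

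Of 14 Paneth genes 11 fell in iDKO and 13 in iTKO libraries at day 30, and of 22 enteroendocrine genes 10 and 13 (adjusted p = 0.276, 0.187, 0.192 and 0.145 as lists with an estimated correlation), which fewer crypt bases in a preparation could also give. Day 6 libraries of the same group that differed in Paneth genes served to predict enteroendocrine from Paneth falls. That they differed in crypt content was assumed, since stem cell genes differed by only -0.11 to -1.05 where Paneth genes did by -2.06 to -5.45. Medians of -0.73 (iDKO, SE across genes 0.14) and -0.81 (iTKO, 0.22) lay below the lowest predictions of -0.49 and -0.57, by less than 2 standard errors. Crypt stem cell genes, at -0.11 and -0.30, lay inside the predicted ranges of -0.54 to -0.08 and -0.63 to -0.09. Crypt content and a lower share of secretory cells cannot be told apart here, and no biological explanation was tested.

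Cholesterol synthesis genes were higher as a list in iDKO at day 30 and in TBX3 iKO (2 of 18 genes called there, camera adjusted p = 0.318 with an estimated correlation), and tamoxifen in the mutants against oil in controls could do that. Against the 2 tamoxifen controls, the 20 genes kept a median log2 of 0.96 (SE across genes 0.16) in iDKO (camera adjusted p = 1.0e-06, adjusted p = 0.43 with an estimated correlation). Library medians of 1.32 and 0.73 against 0.088 and -0.016 argue against tamoxifen alone there. In the TBX3 table, where all controls received oil, library medians of the list were 0.758 (SE between libraries 0.208) higher in TBX3 iKO. The day 30 SMAD controls given tamoxifen stood 0.0423 (SE between libraries 0.270) above those given oil. That is less than tamoxifen alone would need, but those controls also differ in line and Cre, so tamoxifen and TBX3 loss cannot be told apart. No biological explanation was tested.

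Ctrb1, a pancreatic protease gene, stood at 18.9, 7.92 and 19.3 FPKM in the 3 iDKO libraries of day 6 against 0.161, 0.209 and 9.52 in controls (log2 3.14, limma adjusted p = 0.067, not called), and pancreas cells in the preparations could bring it. Cela2a, Cpb1 and Pnlip, abundant in pancreas, reached at most 0.0873 FPKM in those libraries where at least 1.85 was needed at the ratio of the control library that held them, which argues against pancreas cells at day 6. These 3 genes are missing from the day 30 table, so the day 30 rise of Ctrb1 stays open, and no biological explanation was tested.

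Other splits of the same libraries were counted. In the iTKO comparison 1 of 56 splits, the real one, called as many genes (2159 against at most 1 in the others), a share under 0.05. The other splits put mutants and controls in the same group, which widens the spread within groups. Their low counts follow in part from that, so chance is made unlikely but not excluded. In the day 6 iDKO comparison 1 of 10 splits did (2575 against at most 3), with at most 2 in the other splits that parted all 3 numbered pairs, and in TBX3 iKO 1 of 10 (335 against at most 1). With 10 splits, no share under 0.05 can be reached.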

How the results depend on the processing

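The sex covariate, the Paneth gene score covariate and the fit without the libraries low in Paneth genes were chosen after results were seen; the other alternatives were planned. No result changed direction past its test. Of the checks of named genes under the alternatives, 95.7% (53 genes) kept direction and side of the threshold in iDKO at day 6, 96.9% (57) in iDKO at day 30, 98.8% (52) in iTKO, 75.3% (27) in iTKO against iDKO, 77.8% (49) in SMAD4 iKO and 72.4% (42) in TBX3 iKO. For lists these shares were 86.2%, 90%, 90.2%, 88.4%, 91.2% and 78.1%. Under the stricter filter, 13 gene results, such as Ly6d in iDKO and Trim46 in TBX3 iKO, and the day 6 tuft cell list were not tested.

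With an estimated correlation, camera called 0 lists in each of the 6 comparisons. At an unadjusted p under 0.05 it passed 3 in iDKO at day 6, 5 in iDKO at day 30, 6 in iTKO, 2 in iTKO against iDKO, 3 in SMAD4 iKO and 1 in TBX3 iKO. In TBX3 iKO, of the sets taken at adjusted p under 0.05, those higher in iDKO at day 6 (median 0.024) and higher in iTKO (0.068) lost their calls with it. Of the sets of 200 genes of largest statistic, those lower in iDKO at day 6 (-0.316) and lower in iTKO (-0.320) did instead. The stricter filter left 5 list calls in TBX3 iKO. The replicate block ended 17 of 57 gene results in iDKO at day 30, 6 of 52 in iTKO, 19 of 27 in iTKO against iDKO and 25 of 42 in TBX3 iKO.

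Counts of genes higher and lower moved as follows. In iDKO at day 6, 767 were higher after median centring and 1117 after quantile normalization, with 3620 higher and 1360 lower under the Paneth score covariate and 1071 higher without the libraries low in Paneth genes. Leaving out single libraries gave 590 to 1600 higher and 502 to 823 lower. In iDKO at day 30, the replicate block gave 367 and 379, matched controls 649 and 625, and single libraries left out 474 to 1136 and 431 to 1089. In iTKO the replicate block gave 408 and 490, and single libraries left out 593 to 1027 and 653 to 1021.

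In iTKO against iDKO, 13 were higher without the trend, 1 higher and 7 lower with the replicate block, 0 and 7 as a difference of matched effects (886 at an unadjusted p under 0.05 in limma), 5 and 18 with the compared groups alone, 57 and 107 with the sex covariate, and 1 to 153 and 20 to 161 with single libraries left out. In SMAD4 iKO, no filter gave 98 and 135, the replicate block 314 and 520, the Paneth score covariate 618 and 756, and single libraries left out 0 to 37 and 2 to 39 (1527 to 2020 at an unadjusted p under 0.05), where the lone library of a group was assumed to vary like the others. In TBX3 iKO, no filter gave 55 and 71, median centring 135 lower, the replicate block 23 and 17, and single libraries left out 25 to 127 and 22 to 219.

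The correlation of iDKO and iTKO effects at day 30 was 0.656 to 0.772 without single libraries, and the 1334 genes called in the same direction in both became 792 with the controls split by line. Between the 2 kinds of control, 2 genes were higher with the 5 controls alone. The filter changes the number of genes over which p is adjusted, and leaving out libraries lowers their number. For the other shifts the cause was not tested. Without fragment totals, what depth limits could not be measured.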

Other observations

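Further genes with large changes in TBX3 iKO were the ubiquitin-like gene Ubd (83.8 ± 53.5 against 6.34 ± 3.24 FPKM, log2 3.45 ± 0.59), the cell junction gene Ppl (log2 3.29 ± 0.12) and the glutathione transferase gene Gsta1 (105 ± 41.6 against 13.1 ± 7.63 FPKM, log2 3.08 ± 0.57), all higher. Lower were Cyp2j6 (30.5 ± 6.36 against 107 ± 6.24 FPKM, log2 -1.81 ± 0.15), a cytochrome P450 gene, and Akr1c14 (4.42 ± 2.27 against 16.9 ± 3.15 FPKM, log2 -1.90 ± 0.31), a steroid reductase gene. In libraries labelled iDKO at day 6, the lactate and monocarboxylate transporter gene Slc5a12 fell (1.204 ± 0.856 against 91.7 ± 9.08 FPKM, log2 -5.88 ± 0.34), as did Enpp7, which digests sphingomyelin (8.72 ± 3.42 against 266 ± 83.4 FPKM, log2 -4.89 ± 0.35).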
